A study of Mus musculus with 24 samples.

How the data were processed

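RNA of 24 mouse muscle samples was hybridised to Affymetrix arrays, 6 each from quadriceps and soleus of control and nebulin conditional knockout (cKO) males. Per the labels' protocols the mice had a background of 2 strains (C57BL/6J, and 1219S6/SvEvTac as written there), the muscles were kept in RNAlater, total RNA came from a Qiagen RNeasy kit for fibrous tissue, and biotin labelling used a WT Plus kit. The values used are the intensities that the authors deposited, 1 per probe set and array. Per the submitters' processing notes they came from Affymetrix Expression Console with RMA, which corrects background, normalizes quantiles and summarises probe sets, and the genome build was mm10; versions, settings and filters are not given in the sources used here. The deposited intensities are on a linear scale, from 1.76 to 10075, and were turned to log2 before any test. Batches such as slides or scan dates are not given in the sources used here.

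Of 35557 probe sets the annotation table pairs 21789 with 1 gene symbol, 1621 with several and 12147 with none listed here; the last 2 kinds were left out. Symbols were updated through Entrez numbers, by which 21698 probe sets matched a RefSeq table of GRCm38.p6, the assembly that mm10 names. For the 999 genes with more than 1 probe set, among 19938 genes, the probe set with the highest mean over all arrays was used. A gene was kept if its value lay above the array's 30th percentile over all probe sets on at least 6 arrays, which left 15999 genes and removed 3939 dim ones (19.8%). That percentile lay between 3.51 and 3.72 on the log2 scale and served as the dim limit. Where a gene lay below it on every array of a group, its fold is given as a bound, "at least N-fold", from the bright group's mean against the dim group's mean of the higher of the limit and the gene's own value per array. Where a group's mean but not each of its arrays lay at or under the highest dim limit of any array (Cxcl10, Epgn and Tecrl in quadriceps controls, Mettl21e in quadriceps cKO, Mettl11b in both cKO groups, Mstn in soleus cKO), changes against that group are fitted values and not exact.

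Groups came from the sample titles. One limma model of 4 group means was fitted to all 24 arrays (R 4.3.3, limma 3.58.1, lmFit and eBayes with default prior), so that the groups share 1 estimate of the spread per gene with 20 residual degrees of freedom (prior 6.52). It gave cKO minus control in quadriceps and in soleus, the difference of these changes, and soleus minus quadriceps in controls. P-values were adjusted by Benjamini-Hochberg over the 15999 genes and called under 0.05, two-sided. The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from settings said to be chosen after seeing the data.

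Of 32 gene lists 31 had the 3 kept members needed for a test; the red blood cell list, left with Alas2 and Slc4a1, did not. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. With the correlation estimated from the data, the calls that held were the embryonic and denervation lists in both muscles and the denervation list for the difference between muscles. The embryonic and denervation lists share Chrng, Ncam1 and Myog, so their calls are not independent. Other lists overlap too, for example satellite cell and embryonic in Myod1 and Cdh15. The p53 and denervation lists share Gadd45a, and the heat shock and mechanical stress lists share Hspb1, among others. Genes were also counted adjusted over the list alone, and fry was run as an alternative that asks only whether the members move, on balance, 1 way. Named genes are the 12 largest changes each way per cKO comparison and for the difference (6 each way between control muscles) among called genes, leaving out predicted names and small RNA genes of set prefixes, and up to 4 members of each list with the smallest p. The text names fewer list members than this rule allows. Trim63 in both muscles and Fbxo32 in quadriceps fall outside the rule, as does Neb for the difference between muscles.

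The labels give the same numbers 1 to 6 in every group, and arrays of 1 number share their age except quadriceps cKO 4. Whether these pair the samples was checked from the correlation of deviations from the group means over genes. Quadriceps and soleus of 1 genotype and number correlated between 0.16 and 0.31 in controls and between 0.22 and 0.45 in cKO, all 6 pairs of each above 0.1 and each best with its own number, so these were treated as muscles of the same animal in the blocked alternatives, although for 1 number the labels give different ages. Same-numbered arrays of different muscle and genotype, which cannot be 1 animal, correlated as well. Quadriceps control with soleus cKO gave 0.04 to 0.27 (4 of 6 best with their own number), and quadriceps cKO with soleus control -0.04 to 0.28 (3 of 6). Part of the match may thus come from what a number shares across genotypes. The pairing rests on the data, not on a statement in the labels.

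Alternatives were: trend and robust eBayes, no filter, a filter at the 50th percentile, centring on each array's median, quantile normalization, array quality weights, each muscle fitted alone, number and animal blocks, age as a covariate, the mean of a gene's probe sets, an adjusted p under 0.01, a minimum of 1.5-fold, an unequal-variance test per gene, and each array left out in turn. Centring on the 75th percentile, leaving out the 3 arrays of lowest weight, and a fixed block per animal for the difference between muscles were chosen after seeing the data. The pipeline was tested on simulated data with 100 genes changed by each fold among 15999 genes: of genes changed 1.5-fold it recovered 88% in quadriceps, 84% in soleus, 56% for the difference between muscles and 89% between control muscles, and of genes changed 2-fold 98%, 98%, 95% and 97%. False calls numbered 9 of 195, 12 of 194, 6 of 157 and 9 of 195. In that test a shifted gene list was called and 0 of 30 others were, for the quadriceps comparison. The simulated spread was independent between genes and the other lists were random genes. The test therefore does not show how often lists of correlated genes are called falsely. The simulation also changed far fewer genes than were called in the data and gave every array the same spread per gene. Its shares of recovered and false calls need not carry over to the data.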

Results

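Messenger RNA was measured with Affymetrix arrays in the quadriceps and the soleus of male mice aged 40 to 42 days. All mice were homozygous for a conditional allele of nebulin (Neb), which encodes a giant protein that lies along the thin filaments of the sarcomere. In the conditional knockout (cKO) a Cre recombinase driven by a muscle creatine kinase promoter was also present, and the controls lacked it. Each of the 4 groups (quadriceps control, quadriceps cKO, soleus control, soleus cKO) held 6 arrays, described by the labels as biological replicates, so that 24 arrays entered the comparisons. The submitters describe the quadriceps as much smaller in the cKO and the soleus as not significantly so. The array medians over all probe sets lay between 4.74 and 4.94 on the log2 scale. Any pair of arrays of a group correlated with r between 0.963 and 0.993 across genes, and no 2 arrays held identical values. The number of arrays limits the precision: the median standard error of a change was 0.10 on the log2 scale within a muscle and 0.14 for a difference between muscles.

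The first question was whether the targeted transcript was lower where the labels say so. Neb (Entrez gene 17996) lies on chromosome 2 of mm10 between positions 52136640 and 52338798 and was read by 1 probe set. In quadriceps its log2 intensity was 12.29 ± 0.17 (SD, n = 6) in controls and 10.84 ± 0.23 (SD, n = 6) in cKO, which is 2.73-fold lower (log2 change -1.45, SE 0.11, limma adjusted p = 1.41e-10). In soleus it was 12.38 ± 0.21 in controls and 11.25 ± 0.20 in cKO (SD, n = 6 each), 2.20-fold lower (log2 change -1.14, SE 0.11, adjusted p = 2.27e-08). Every cKO array read below every control array of its muscle. The loss did not pass the test for a difference between the muscles (-0.31, SE 0.16, adjusted p = 0.215). The labels used here do not give the deleted part of the gene or the place of the probes, so the remaining signal cannot be assigned to intact or shortened transcripts.

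**Figure D1:**
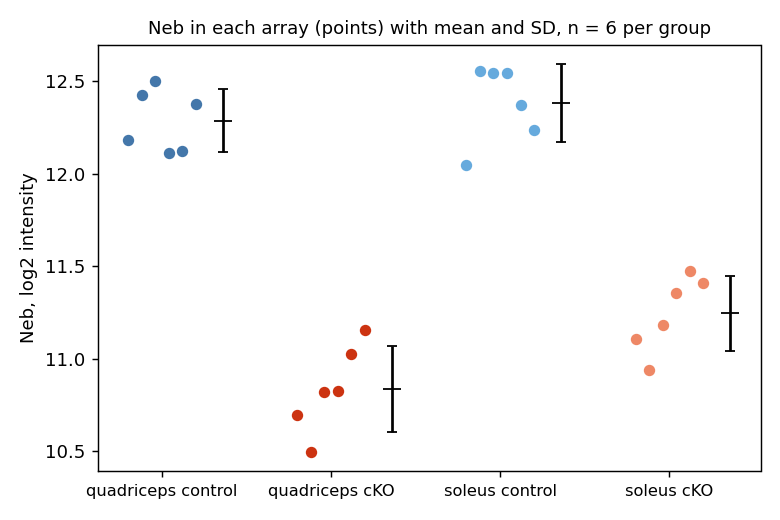
Log2 intensity of Neb in each array (points) with the mean and SD of each group of 6 arrays (bars), for control and cKO quadriceps and soleus. Control arrays lie between 12.04 and 12.56 and cKO arrays between 10.50 and 11.48, with no overlap.

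The quadriceps comparison asked which transcripts differ in the muscle that was smaller in the cKO. The embryonic myosin heavy chain Myh3 rose 41.7-fold (log2 change 5.38, SE 0.40), the aldehyde dehydrogenase Aldh3a1 rose 18.4-fold, the stretch-responsive ankyrin repeat protein Ankrd1 16.2-fold and the desmosome protein Dsp 15.5-fold. Fam171b, the small GTPase Rrad, the calcium pump inhibitor Sln, Ttc9, Tecrl, the Z-disc protein Csrp3, tyrosine hydroxylase (Th) and the transcription factor Runx1 followed, with log2 changes between 3.56 for Fam171b and 2.88 for Runx1. The largest losses were in the methyltransferase Mettl21e (log2 change -2.72) and in myostatin (Mstn, -2.70, 6.49-fold lower), the secreted inhibitor of muscle growth. Cyp4f39, Nt5c1a, Mettl11b, St8sia5, Chac1, the glucose-6-phosphate transporter Slc37a4, the methyltransferase Smyd2, the potassium channel subunit Kcng4 and neuronal nitric oxide synthase (Nos1) fell by 2.45 for Cyp4f39 to 1.90 for Nos1 on the log2 scale. Odf3l2 was not above the dim limit in any cKO array and was at least 3.48-fold lower. Over the 15999 genes tested, 6399 passed an adjusted p of 0.05 in limma, 3563 higher and 2836 lower in cKO, of which 1068 and 544 changed at least 1.5-fold.

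The lists of slow fibre and of immature muscle genes were both called higher in cKO quadriceps. All 12 members of the slow fibre contractile list were higher, with a median log2 change of 1.94, among them slow troponins I (Tnni1, 2.53) and C (Tnnc1, 2.35), the light chain Myl6b (2.54) and calsequestrin 2 (Casq2, 2.17). The list was called (camera adjusted p = 6.82e-12), with adjusted p = 0.12 with an estimated correlation. Of 15 embryonic and neonatal muscle genes 12 rose and none fell (median 1.68), led after Myh3 by neonatal myosin Myh8 (2.81), the adhesion molecule Ncam1 (2.59) and myogenin (Myog, 2.54). This call held (adjusted p = 0.0139 with an estimated correlation). In the fast fibre contractile list 10 of 16 fell, among them Mylk2 (-1.41) and fast troponin I (Tnni2, -0.52), and 1, the type IIa myosin Myh2, rose (1.01). The median was -0.32, with adjusted p = 0.326 with an estimated correlation. Inside the lists alone the counts were 12 higher for the slow list, 12 higher and 1 lower for the embryonic list, and 1 higher and 12 lower for the fast list.

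The denervation and neuromuscular junction list also rose, with 13 of 21 members higher and 2 lower (median 0.50), and held with adjusted p = 0.00209 with an estimated correlation. Besides Runx1 and Ncam1 these included the fetal and delta subunits of the acetylcholine receptor, Chrng (1.87) and Chrnd (1.77). Chrng, Ncam1 and Myog are also members of the embryonic list, so the calls of these lists, here and in soleus, are not independent. Of 22 mechanical stress and sarcomere repair genes 17 rose and 3 fell (median 0.75), with Ankrd1, Csrp3 and Fhl2 (1.74) in front. Its adjusted p was 0.155 with an estimated correlation. In the growth signalling list 16 of 31 rose and 5 fell (median 0.32, adjusted p = 0.12 with an estimated correlation): the myostatin antagonist follistatin (Fst, 1.92) and Igf2 (1.68) were higher while Mstn was lower. Adjusted over the list alone, 14 members were higher and 3 lower for denervation, 17 and 3 for mechanical stress, and 18 and 5 for growth signalling.

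Lists of energy metabolism genes were called lower in cKO quadriceps, though not with an estimated correlation. Of 73 oxidative phosphorylation genes 57 were lower and none higher (median -0.37), for example complex I subunits Ndufb2 (-0.77) and Ndufb8 (-0.75) and the cytochrome oxidase subunit Cox8b (-0.71). In the glycolysis and glycogen list 18 of 21 fell and none rose (median -0.53), led by phosphorylase kinase subunits Phkg1 (-1.46) and Phka1 (-1.09). Of 25 fatty acid oxidation genes 13 fell and 1 rose (median -0.30), with Acadvl at -0.44 and Echs1 at -0.41. The adjusted p-values with an estimated correlation were 0.12, 0.155 and 0.492 in that order. By the adjustment inside each list, 60 oxidative phosphorylation, 18 glycolysis and 13 fatty acid oxidation genes were lower, with 0, 1 and 1 higher.

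Lists of matrix genes and of markers of other cells were called higher in the same arrays, none of them with an estimated correlation. The extracellular matrix list had 28 of 32 members higher and none lower (median 0.58, adjusted p = 0.169 with an estimated correlation), led by periostin (Postn, 2.28), Thbs1 (1.49) and Ccn2 (1.48). Macrophage genes were higher in 16 of 20 and lower in none (median 0.72, adjusted p = 0.155 with an estimated correlation), with Lgals3 (1.81), Mpeg1 (1.62) and Cd68 (1.15). Fibro-adipogenic progenitor genes rose in 7 of 11 and fell in 1 (median 0.35), with Mfap5 at 1.39, and adipocyte genes rose in 8 of 14 (median 0.71), with Cidec at 1.26. Satellite cell genes, those of muscle stem cells, rose in 8 of 13 (median 0.39), with Myod1, also in the embryonic list, at 1.06. For these the adjusted p was 0.326, 0.542 and 0.156 with an estimated correlation. None of the 14 endothelial and none of the 7 lymphocyte genes passed the test (medians -0.04 and -0.07, list adjusted p = 0.761 and 0.535), with Kdr at -0.44 (adjusted p = 0.0748). Kdr passed without quadriceps control 4, cKO 2 or cKO 4 (down to 0.0182) and under each other scaling (down to 0.0163). Tested within the list, 28 matrix, 16 macrophage, 7 progenitor, 10 adipocyte and 8 satellite cell genes were higher, and 1 progenitor gene was lower. The red blood cell list kept 2 members and was not tested.

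Stress genes moved in part. Cytosolic heat shock genes rose in 10 of 17 and fell in 1 (median 0.43), with Hspa1a at 1.63 and Hspb1 at 1.40, endoplasmic reticulum chaperones in 12 of 18 (median 0.41), with Pdia3 at 0.73, and p53 targets in 9 of 17 with 2 lower (median 0.35), with Eda2r at 2.48 and Gadd45a at 1.62. Cell cycle genes rose in 8 of 22 and fell in 1 (median 0.23), with the replication factor Mcm6 at 2.20 and Kif11 at 0.94. These 4 lists had adjusted p-values of 0.266, 0.355, 0.172 and 0.27 with an estimated correlation. Adjusted over the list alone, 10 heat shock genes were higher and 1 lower, 14 chaperones higher and 1 lower, 9 p53 targets higher and 2 lower, and 9 cell cycle genes higher and 1 lower. The ligases known from muscle wasting, chosen here after their values were seen, were at -0.18 for Trim63 (adjusted p = 0.417) and -0.05 for Fbxo32 (adjusted p = 0.82), while Fbxo30 rose by 1.11, Foxo1 rose by 1.01 and Fbxo31 fell by 1.35. The atrophy list as a whole had 8 of 29 members higher and 3 lower (median 0.03, adjusted p = 0.744).

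The remaining quadriceps lists were not called either. They were thin filament and Z-disc (9 of 35 higher, 10 lower, median -0.02, adjusted p = 0.634), proteasome (8 of 31 higher, 2 lower, 0.09, 0.364), pericyte and smooth muscle (2 of 11 higher, 1 lower, 0.02, 0.696), tendon (1 of 10 higher, 1 lower, -0.07, 0.696) and Schwann cell and nerve (2 of 10 higher, 2 lower, 0.07, 0.696). Integrated stress response (6 of 20 higher, 4 lower, 0.16, 0.535), circadian clock (2 of 15 higher, 2 lower, -0.25, 0.535) and immediate early genes (5 of 24 higher, none lower, 0.12, 0.331) were also not called, although Atf3, which the first and last of these share, rose by 2.74. Within the thin filament list Lmod2 rose by 1.14. Median, mean and test differed in sign for calcium handling (4 of 25 higher, 8 lower, median -0.12, mean 0.06, test down, adjusted p = 0.22), where Sln and Casq2 rose while myoregulin (Mrln, -1.51) and junctophilin 2 (Jph2, -1.13) fell. They also did so for polyamine and methionine genes (2 of 7 higher, 1 lower, median 0.10, mean -0.02, test up, adjusted p = 0.696), where Smox fell by 1.67. Counted within single lists, the counts of these and the other lists not called stayed as given, except 10 and 10 for thin filament, 4 and 9 for calcium handling, 5 and 2 for proteasome, 2 and 1 for clock and 4 and 0 for immediate early genes.

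Of the 71 genes named above that were called in quadriceps, 66 had all 6 cKO arrays beyond all 6 control arrays, which chance gives for 0.216% of unselected genes. Here and below such counts describe the arrays and are no test, since the genes were named for large changes or small p. The exceptions were Acadvl, Cidec, Foxo1, Mettl21e and Pdia3. The progenitor call was lost with array quality weights (adjusted p = 0.0531), with the stricter filter (0.055) and without the 3 arrays of lowest weight (0.0949), and the p53 (0.0892) and cell cycle calls (0.0856) were lost with that filter. The balance of higher and lower calls in quadriceps rested on the scaling: 55.7% of called genes were higher with the values as deposited, 29.2% with each array centred on its median, 35.8% on its 75th percentile and 47.0% after quantile normalization. Median centring moved the median change of all genes from -0.01 to -0.14, and the 75th percentile moved it to -0.11. No named gene and no called list of the quadriceps turned its direction under these scalings, while the medians of 7 lists not called changed sign under at least 1 of them (thin filament, atrophy, proteasome, pericyte, Schwann cell, polyamine and immediate early).

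In the soleus, which was not significantly smaller, the same comparison found fewer genes, 3694 against 6399 in the shared fit. With each muscle fitted on its own arrays the gap was smaller, 4237 against 5333. Part of the gap thus rests on fitting all arrays together. Mybph, a myosin-binding protein, rose 21.1-fold (log2 change 4.40, SE 0.23), and Myh3 rose 15.2-fold (3.93). Fam171b (3.44), the retinol carrier Rbp4 (3.41), Dsp (3.39), the stress-induced transcription factor Atf3 (3.18), Ankrd1 (3.16), the ubiquitin hydrolase Uchl1 (2.81), Eda2r (2.77) and Ndrg4 (2.69) followed. Muc15 and Epgn were not above the dim limit in any control array and were at least 6.82-fold and at least 8.75-fold higher. Losses were led by fast fibre genes: parvalbumin (Pvalb, -2.96, 7.77-fold lower), the fast myosin-binding protein Mybpc2 (-2.94) and the type IIb myosin Myh4 (-2.56). Mylk4, Smco1, Lrrc52, Mettl11b, Lrtm1, the epoxide hydrolase Ephx2, the ketone body enzyme Bdh1, the tendon and cornea proteoglycan keratocan (Kera) and Aldh1a1 fell by 2.31 for Mylk4 to 1.82 for Aldh1a1. In all, 3694 genes passed, 2104 higher and 1590 lower in cKO, of which 590 and 424 changed at least 1.5-fold.

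Fast fibre contractile genes fell in 11 of 16 and rose in none (median -0.58, adjusted p = 0.085 with an estimated correlation), including Tnni2 (-0.91). Of the 12 slow fibre contractile genes 4 rose and 1 fell (median 0.33, camera adjusted p = 0.00592, adjusted p = 0.459 with an estimated correlation): Myl6b (2.22), Casq2 (0.90) and Tnni1 (0.81) were among those higher. Embryonic and neonatal muscle genes rose in 13 of 15 (median 1.0) and held with adjusted p = 0.00904 with an estimated correlation, with Myog at 1.81 and Ncam1 at 1.41 besides Mybph and Myh3. The denervation and neuromuscular junction list rose in 11 of 21 and fell in 3 (median 0.36) and held with the same adjusted p = 0.00904 with an estimated correlation, with the acetylcholine receptor subunit Chrnb1 at 1.48 and Runx1 at 1.22. Adjusted over the list alone the counts were 0 higher and 11 lower, 4 and 1, 13 and 0, and 12 and 3 in that order. Myosin heavy chains and actins are near-identical in sequence, so Myh1, Myh2, Myh4, Myh8 and Actc1 may have been read in part through each other's probes.

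Mechanical stress and sarcomere repair genes rose in 15 of 22 and fell in 1 (median 0.44, adjusted p = 0.063 with an estimated correlation), with Hspb1 at 1.89 and Xirp2 at 0.87. Proteasome subunits rose in 22 of 31 and fell in none (median 0.36, adjusted p = 0.054 with an estimated correlation), with Psmd11 and Psmc4 both at 0.77. Fatty acid oxidation genes fell in 21 of 25 (median -0.64, adjusted p = 0.063 with an estimated correlation), among them Eci1 (-0.87) and Acadvl (-0.68). Oxidative phosphorylation genes fell in 44 of 73 (median -0.29), with Uqcrc1 at -0.60 and Sdhb at -0.53, and glycolysis and glycogen genes in 15 of 21 (median -0.38), with Phkg1 at -1.02 and hexokinase 2 (Hk2) at -0.75. For the last pair the adjusted p was 0.085 and 0.118 with an estimated correlation, and no member of these 3 metabolic lists rose. By the adjustment inside each list, 16 mechanical stress genes were higher and 2 lower, 24 proteasome genes were higher, and 21, 50 and 15 metabolic genes were lower.

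Matrix and macrophage lists were called higher in the soleus as well, with 16 of 32 (median 0.36) and 14 of 20 (median 0.52) higher and none lower, and vessel lists were called lower, none of them with an estimated correlation. Postn rose by 1.74, Loxl1 by 1.03, Cd68 by 2.10 and Mpeg1 by 0.93. Adjusted p-values with an estimated correlation were 0.215 for matrix and 0.118 for macrophages. Endothelial genes fell in 10 of 14 (median -0.37, adjusted p = 0.133 with an estimated correlation), with the receptors Kdr at -1.17 and Flt1 at -0.68. Pericyte and smooth muscle genes fell in 5 of 11 and rose in 1 (median -0.36), where Myh11 was at -0.66 and Cspg4 at 0.62. Tendon genes fell in 7 of 10 and rose in 1 (median -0.62), with Mkx at -0.67. The last pair shared adjusted p = 0.215 with an estimated correlation. Fibro-adipogenic progenitor genes rose in 4 of 11 (median 0.08, adjusted p = 0.255 with an estimated correlation), with Mfap5 at 1.60. Adjusted over the list alone, 20 matrix, 14 macrophage and 4 progenitor genes were higher, 13 endothelial genes lower, 8 tendon genes lower and 1 higher, and 6 pericyte genes lower and 1 higher.

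Smaller sets completed the soleus pattern. Cell cycle genes rose in 9 of 22 (median 0.26), with Mcm6 at 1.78 and Prc1 at 1.34, and p53 targets in 6 of 17 with 1 lower (median 0.12), with Zmat3 at 1.05. Cytosolic heat shock genes rose in 8 of 17 with 1 lower (median 0.23), with Hspa1a at 1.35, and polyamine and methionine genes in 3 of 7 (median 0.26), with Odc1 at 1.0 and Sat1 at 0.55. In that order the adjusted p was 0.118, 0.118, 0.215 and 0.063 with an estimated correlation. Satellite cell genes rose in 4 of 13 (median 0.16, camera adjusted p = 0.0313, adjusted p = 0.255 with an estimated correlation). Among them Cdh15, also in the embryonic list, rose by 0.56. The satellite cell call was lost without soleus cKO 2 (0.0682), cKO 3 or control 5. The endoplasmic reticulum chaperones narrowly missed (3 of 18 higher, median 0.19, adjusted p = 0.0505) and passed without any of 14 arrays, down to 0.011, without a filter (0.0176), with each muscle fitted alone (0.0279), with the number as a block (0.0324) and with arrays centred on the 75th percentile (0.0374) or the median (0.0452). With p adjusted inside each list, 11 cell cycle, 5 polyamine, 4 satellite cell and 3 chaperone genes were higher, 6 p53 targets were higher and 2 lower, and 9 heat shock genes were higher and 1 lower.

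The lists not called in soleus were thin filament and Z-disc (11 of 35 higher, 11 lower, median 0.06, adjusted p = 0.362), where Klhl40 rose by 1.45 and Pdlim3 by 0.92, calcium handling (7 of 25 higher, 5 lower, 0.16, 0.324), where Sln rose by 2.08, and growth signalling (8 of 31 higher, 6 lower, 0.10, 0.324), where Gdf11 rose by 1.57 and Fst by 1.21. The atrophy list (5 of 29 higher, 3 lower, 0.09, 0.362) held higher Map1lc3a (0.92) and Sqstm1 (0.37) and lower Fbxo31 (-0.69), Fbxo32 (-0.58, adjusted p = 0.00625) and Trim63 (-0.50, adjusted p = 0.0314). Lymphocyte (0 of 7 higher, 1 lower, -0.08, 0.362), adipocyte (2 of 14 higher, 0.35, 0.15) and integrated stress response genes (3 of 20 higher, 3 lower, 0.11, 0.362) were not called. With each muscle fitted alone the adipocyte list was called (0.0289), and by fry the growth list (0.0199). In the adipocyte list Car3, which slow muscle fibres also express, rose by 0.45, a call lost after quantile normalization (adjusted p = 0.064). Median, mean and test differed in sign for Schwann cell and nerve (1 of 10 higher, median -0.05, mean 0.06, test up, 0.905), circadian clock (2 of 15 higher, median -0.14, mean -0.00, test up, 0.967) and immediate early genes (3 of 24 higher, median -0.03, mean 0.12, test up, 0.623). Counted within single lists, the counts of the lists not called stayed as given, except 13 and 11 for thin filament, 10 and 5 for calcium handling and 6 and 4 for atrophy genes. Of 71 named genes called in soleus 65 had all 6 cKO arrays beyond all 6 control arrays, and the exceptions were Cspg4, Fbxo31, Fbxo32, Mybpc2, Myh4 and Trim63. Trim63 lost its call without soleus control 2, control 3, cKO 1, cKO 4 or cKO 5 (up to 0.107), the p53 list with the stricter filter (0.0623), the satellite cell list after quantile normalization (0.0641) and the progenitor list without the 3 arrays of lowest weight (0.0543). Of the called genes 57.0% were higher, against 51.6% after median centring and 45.2% after centring on the 75th percentile.

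Genes called in both muscles mostly changed in 1 direction. In quadriceps but not soleus 4108 genes were called, and in soleus but not quadriceps 1403. Of these 1107 and 388 passed the test of the difference. The gap between 4108 and 1403 also rests in part on fitting all arrays together. Of the genes called in both, 1350 were higher in both and 824 lower in both, where independent lists of these lengths would share 468.6 and 281.9. Another 117 ran in opposite directions, 54 of them higher in quadriceps and lower in soleus, so that 94.9% of the shared calls had 1 direction. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.63 and rho = 0.52. Because a quadriceps and a soleus of 1 genotype and number deviated together, the correlation was also taken between arrays of different numbers, where it was 0.54 and 0.61, against 0.62 and 0.58 for arrays of the same numbers. Myh3, Dsp, Fam171b and Ankrd1 rose and Mettl11b and Neb fell in both. The count of opposite genes rose to 191 without quadriceps control 6 and to 197 without soleus control 1.

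The difference between the muscles was itself tested, as the quadriceps change minus the soleus change. The change was more positive in quadriceps for Aldh3a1 (4.20 against 0.76), the secreted peptide gene Ostn (2.65 against -0.53, the latter not past the test), Krt18 (2.86 against 0.57), Rrad (3.47 against 1.19), the chemokine Cxcl10 (2.36 against 0.13, not past the test) and the inositol transporter Slc5a3 (0.48, not past the test, against -1.58). It was more positive in soleus for Mybph (0.39 in quadriceps, not past the test, against 4.40), the small RNA Rny1 (-1.55 against 1.63), Cyp4f39 (-2.45 against -0.25, not past the test), the cardiac actin Actc1 (-0.53, not past the test, against 1.60), Aimp2 (-1.24 against 0.68) and the kinase subunit Prkab2 (-0.93 against 0.80). Gamt rose by 1.82 in soleus and stood at 0.07 in quadriceps (adjusted p = 0.763). For Muc15, Epgn and Rbp4 the rise was larger in soleus (differences of -1.54, -1.79 and -1.78), and for Mstn and Slc37a4 the fall was larger in quadriceps (-1.85 and -1.57). In soleus cKO the mean of Mstn (3.47) lay at the dim limit, and Muc15 and Epgn were dim in soleus controls, Muc15 in quadriceps controls too, and the mean of Cxcl10 in quadriceps controls (3.69) lay near that limit, so these 4 differences are not exact. Altogether 1966 genes passed, 1183 with a more positive change in quadriceps and 783 with a more positive one in soleus. The change was the larger in size in quadriceps for 1398 of them and in soleus for 568.

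Among the lists, slow fibre contractile genes separated the muscles most by median (median difference 1.55, adjusted p = 0.168 with an estimated correlation). Of the 12 members 10 passed, all more positive in quadriceps, with Myh7 at 1.93, Tnnc1 at 1.76 and Myl2 at 1.57. In controls all 12 already stood higher in soleus (median 2.50), and whether this limited their rise there was not tested. The denervation list passed in both tests (9 of 21 more positive in quadriceps, 1 in soleus, median 0.41, adjusted p = 0.0406 with an estimated correlation), with Chrna1 at 1.76, Runx1 at 1.66 and Chrng at 1.51. Proteasome genes were more positive in soleus in 14 of 31 (median -0.33, adjusted p = 0.168 with an estimated correlation), with Psmd4 at -0.66 and Psmd8 at -0.52. Fatty acid oxidation genes were more positive in quadriceps in 7 of 25 (median 0.30, adjusted p = 0.394 with an estimated correlation), including Lpl (1.04) and Cd36 (0.75). Embryonic and neonatal genes (8 of 15 more positive in quadriceps, 2 in soleus, median 0.73, adjusted p = 0.31 with an estimated correlation), growth signalling (8 of 31 and 2, 0.22, 0.269), endothelial (4 of 14, 0.43, 0.381), pericyte and smooth muscle (4 of 11, 0.37, 0.381), tendon (2 of 10, 0.49, 0.547) and extracellular matrix (3 of 32, 0.25, 0.725) were also called, each p here with an estimated correlation. Adjusted over the list alone, members more positive in quadriceps and in soleus numbered 10 and 0 for slow fibre, 11 and 4 for denervation, 0 and 19 for proteasome, 11 and 0 for fatty acid oxidation, 10 and 3 for embryonic, 11 and 3 for growth, 8 and 0 for endothelial, 4 and 0 for pericyte, 8 and 1 for tendon, and 2 and 0 for matrix genes.

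The fast fibre list was called more positive in quadriceps, with 7 of 16 members more positive there and 2 in soleus (8 and 3 adjusted over the list alone). Its median was 0.26 with camera adjusted p = 0.0397, or adjusted p = 0.724 with an estimated correlation. Members more positive in quadriceps included Pvalb (2.30) and Myh1 (1.72), and Myh4 (2.33, adjusted p = 0.0486) lost its call without any of 20 arrays, up to 0.0904. The fast list lost its call with the animal as a fixed block (adjusted p = 0.065), without quadriceps control 6, cKO 1 or cKO 5, and without soleus control 3, control 5, control 6, cKO 4 or cKO 6 (up to 0.101). Endoplasmic reticulum chaperones had no member past the test (0 of 18, median 0.23, camera adjusted p = 0.0428, adjusted p = 0.724 with an estimated correlation) and lost their call without any of 12 arrays, up to 0.136. Growth signalling lost its call without quadriceps control 1 (0.0523) and extracellular matrix without soleus cKO 6 (0.0553). The stricter filter ended the calls of pericyte (0.0531), growth (0.0561), fast fibre (0.0657) and chaperone genes (0.0733), and array quality weights those of fast fibre (0.0626), growth (0.0721), matrix (0.129) and chaperone genes (0.134). By fry the fast fibre (0.107), matrix (0.196) and chaperone lists (0.202) were not called. Without the 3 arrays of lowest weight (quadriceps control 4 and 6, soleus control 1), a setting chosen after seeing the data, the embryonic (0.062), growth (0.062), matrix (0.14), tendon (0.0616) and chaperone lists (0.148) were not called and 3675 genes passed. The count of 1966 genes was 2952 with the animal as a random block, a set that held all 1966, and 2856 without quadriceps control 6.

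The lists not called for the difference, each with its median and adjusted p, were thin filament and Z-disc (-0.07, 0.0888), mechanical stress (0.06, 0.628), atrophy (-0.06, 0.628), oxidative phosphorylation (-0.06, 0.0522), glycolysis (-0.18, 0.0777), macrophage (0.12, 0.186), lymphocyte (0.01, 0.979), adipocyte (0.53, 0.102), satellite cell (0.17, 0.217), Schwann cell and nerve (0.04, 0.925), p53 (0.04, 0.925), cytosolic heat shock (0.10, 0.57), polyamine (-0.11, 0.0522), circadian clock (-0.10, 0.413) and immediate early (0.14, 0.628). Median, mean and test differed in sign for calcium handling (median -0.30, mean 0.04, test down, 0.0522), fibro-adipogenic progenitor (-0.10, 0.01, up, 0.925) and cell cycle genes (0.04, 0.03, down, 0.976). Within the macrophage list Cd68 rose more in soleus (difference -0.95). In the integrated stress response list all 3 were below 0 (-0.04, -0.02, down, 0.925). Other settings called some of these lists: calcium handling with array quality weights, age or the mean of probe sets (down to 0.0309), oxidative phosphorylation with median centring, age or the number as a block (down to 0.0264), and adipocyte genes with median centring or quantile normalization (down to 0.0262). Polyamine genes were called without a filter, after quantile normalization, with weights, age or the mean of probe sets (down to 0.0463) and by fry (0.00637). Leaving out any of 7, 6 and 6 single arrays also called calcium handling, oxidative phosphorylation and polyamine genes. The same held for adipocyte (without quadriceps control 3 or soleus cKO 3, down to 0.00436), macrophage (without quadriceps control 3 or 4, down to 0.0398), glycolysis (without quadriceps control 4, cKO 4 or cKO 5 or soleus control 3 or 6, down to 0.0191) and thin filament genes (without quadriceps control 4, 0.0306).

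**Figure D2:**
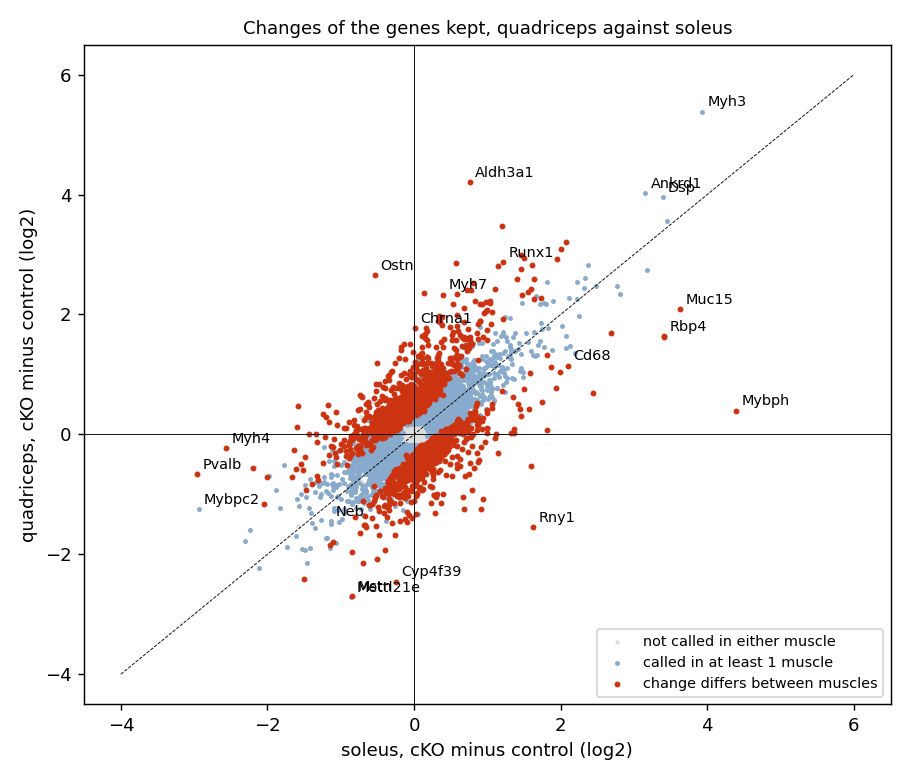
Log2 change (cKO minus control) of each gene in soleus (horizontal) and quadriceps (vertical), with the broken line marking equal change; red points are the 1966 genes whose change differed between the muscles. Myh3, Ankrd1 and Dsp lie high in both muscles, Aldh3a1 lies high in quadriceps and Mybph in soleus.

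**Figure D3:**
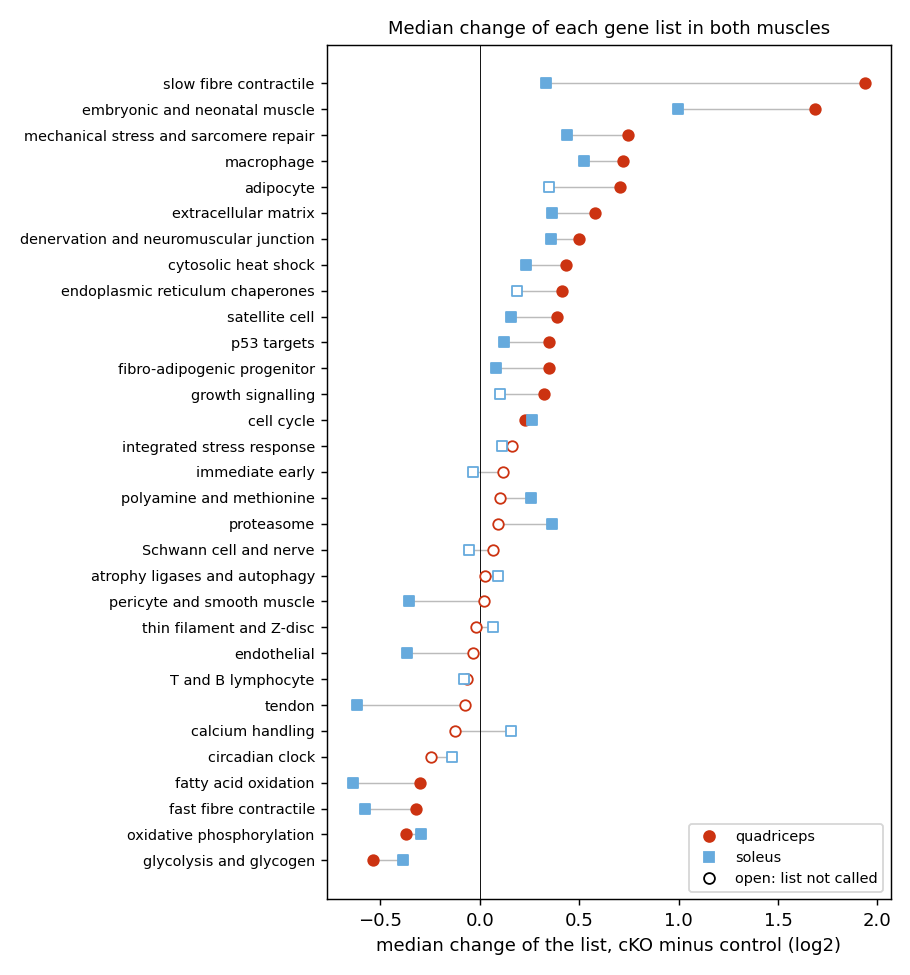
Median log2 change (cKO minus control) of the 31 tested gene lists in quadriceps (circles) and soleus (squares); open symbols mark lists that camera did not call. Slow fibre contractile genes stand at 1.94 in quadriceps and 0.33 in soleus, and proteasome genes at 0.09 and 0.36.

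The control muscles give the background on which both responses are read. Soleus exceeded quadriceps in slow fibre genes, with Tnnc1 higher by 3.09, Tnni1 by 3.0, Myh7 by 2.78 and Myl3 by 2.50 on the log2 scale, and in Tecrl (4.49, not exact, since its quadriceps mean of 3.13 lay under the dim limit), Lgi1 (3.79) and P3h2 (2.73). It was lower in Mstn (-4.32, 19.9-fold), Tspan8 (-3.89), Mss51 (-3.87), the uncoupling protein Ucp1 (-3.84), Mybph (-3.67) and Mybpc2 (-3.32). Of 5362 genes past the test 2434 were higher and 2928 lower in soleus. All 12 slow fibre genes were higher (median 2.50), and of 16 fast fibre genes 14 were lower and 1 higher (median -0.60), with Pvalb at -2.55 and Mylk2 at -1.65. Fatty acid oxidation genes were higher in 16 of 25 and lower in 2 (median 0.37), with Lpl at 1.09 and Hadhb at 0.51, and glycolysis genes were lower in 16 of 21 and higher in 2 (median -0.80), with Phkg1 at -2.18. Proteasome genes were lower in 24 of 31 (median -0.42), with Psmc5 at -0.63. These 5 lists had adjusted p = 0.0693, 0.1, 0.401, 0.1 and 0.1 with an estimated correlation.

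Calcium handling (15 of 25 lower, 5 higher, median -0.37, adjusted p = 0.189 with an estimated correlation), endothelial (8 of 14 higher, 0.35, 0.448) and tendon genes (8 of 10 higher, 0.63, 0.393) were called as well. Mechanical stress genes (11 of 22 higher, 7 lower, 0.26, camera adjusted p = 0.0454, adjusted p = 0.693 with an estimated correlation) lost the call without quadriceps control 4, control 5 or cKO 3, or soleus control 1, cKO 5 or cKO 6 (up to 0.0979), and under several other settings (up to 0.179). Oxidative phosphorylation genes (21 of 73 lower, 4 higher, -0.07, camera adjusted p = 0.0428, adjusted p = 0.865 with an estimated correlation) lost it without quadriceps control 4 or 5 or soleus control 2, 4 or 5 (up to 0.261), with the animal as a fixed block (0.058) and under several other settings (up to 0.375). Pericyte and smooth muscle genes (5 of 11 higher, 0.26, adjusted p = 0.0511) passed with that block (0.035), without any of 6 arrays (down to 0.0162) and under several other settings (down to 0.0016 by fry). In all 19 named genes every soleus array lay beyond every quadriceps array, 6 against 6. Tested within the list, 12 slow and 17 fatty acid oxidation genes were higher and 14 fast, 16 glycolysis, 26 proteasome, 16 calcium handling and 21 oxidative phosphorylation genes lower. In the same way 13 mechanical stress genes were higher and 7 lower, and 9 endothelial, 8 tendon and 5 pericyte genes were higher.

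The other lists were not called between control muscles, with medians and adjusted p of -0.01 and 0.613 for embryonic, -0.11 and 0.27 for atrophy, 0.02 and 0.823 for denervation, 0.06 and 0.0818 for matrix, -0.07 and 0.442 for macrophage, 0.02 and 0.734 for lymphocyte, -0.62 and 0.15 for adipocyte, and -0.09 and 0.0551 for fibro-adipogenic progenitor genes. They were 0.22 and 0.259 for satellite cell, -0.01 and 0.728 for Schwann cell, -0.09 and 0.103 for p53, -0.10 and 0.459 for chaperones of the endoplasmic reticulum, -0.05 and 0.732 for heat shock, -0.07 and 0.15 for polyamine, -0.12 and 0.544 for clock, and 0.08 and 0.746 for immediate early genes. Median, mean and test differed in sign for thin filament (median 0.03, mean -0.09, test down, 0.728), growth (0.04, -0.14, down, 0.847), cell cycle (0.02, -0.01, down, 0.924) and integrated stress response genes (0.01, -0.07, down, 0.783). Progenitor genes were called without a filter, with weights or age, without the 3 arrays of lowest weight (0.0295 to 0.04) and without any of 5 single arrays, and matrix genes with the stricter filter (0.0462), after quantile normalization (0.00902) and without quadriceps control 3 or soleus control 4 (down to 0.00307). By fry progenitor (0.00198), p53 (4.1e-04) and polyamine genes (4e-05) were called. Centring on the 75th percentile moved the median difference of all genes from 0.03 to 0.11, and the oxidative phosphorylation median from -0.07 to 0.01 with the call lost. The medians of 7 lists not called between control muscles and of 5 not called for the difference also changed sign under at least 1 other scaling.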

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

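The tests of the Neb value of soleus control 1, of the scaling behind the slow fibre list and of the clock genes were chosen only after the result was seen. An array stood apart when its gap to the nearest of its group divided by the group's range exceeded Dixon's 95% critical value for 6 samples, which chance gives in about 1 in 20 groups. Over 403 groups of named gene values this marked 40, where chance gives 20.1, and over 124 groups of list means it marked 14, where chance gives 6.2. Soleus control 1 held 21 of these and soleus cKO 6 held 6.

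Soleus control 1 lay apart from the other soleus controls in several named genes. Its log2 value was above the other 5 in Myh3 (9.80), Mybph (8.17), Actc1 (10.60), Rbp4 (6.77), Ndrg4 (6.75), Klhl40 (8.06), Hspb1 (10.35), Fst (7.38), Casq2 (10.89), Tnni1 (12.19), Myh7 (12.92), Myl3 (11.92), Cspg4 (7.03), Psmc4 (8.16) and Psmd8 (9.35). It was below them in Mylk4 (7.54), Myh1 (10.81), Mstn (3.31) and Tspan8 (3.5). Most of these differences run in the direction of the soleus cKO change, except that Myl3 was lower in cKO soleus (-0.34) and Myh7 was not called there. Its mean was higher over the slow fibre list (11.63, others 10.99 to 11.15) and the embryonic list (7.30, others 6.50 to 6.78).

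Neb read 12.04 in the array, below the other soleus controls (12.24 to 12.56) and above the highest soleus cKO array (11.48, SD of those arrays 0.20), which argues against a whole cKO sample under this control label. RNA of a cKO soleus mixed into the sample would give equal shares over all genes if intensity is proportional to RNA amount. The median share of the cKO profile was 0.23 over 213 genes higher in cKO and 0.62 over 123 genes lower. The difference was -0.40 (95% bootstrap interval over genes -0.46 to -0.29). Only under that proportion, which was not tested on these arrays, does this argue against mixing as the whole cause. Mixing as a part of the cause stays open, since Neb itself stood at a share of 0.44 towards cKO. A state of the whole animal remains possible, since quadriceps control 1, its partner by number, ranked 1 of 6 quadriceps controls along the quadriceps cKO profile, at 0.21 against 0.12 for the next. Chance alone gives that rank 1 time in 6, so it is weak support. The soleus array itself stood at 0.38 and the other soleus controls between -0.07 and -0.01. Without soleus control 1 the count of genes with opposite changes was 197.

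All 12 slow fibre genes were higher in cKO quadriceps, by a median of 1.94. The lowest median over the other scalings was 1.81, so the rise did not rest on the choice among them. Median centring, the largest shift, moved the median quadriceps change of all genes only from -0.01 to -0.14. These scalings could therefore hardly have removed a rise of this size. Slow muscle tissue taken along with the cKO quadriceps would bring other soleus-enriched genes to the same share. Their median share over that of the slow list was 0.54 (95% interval 0.33 to 0.77) with quadriceps controls 1 to 3 as the baseline of the muscle difference and 0.867 (0.61 to 1.13) with controls 4 to 6, and the shares of the slow list itself were 0.55 and 0.54 and those of quadriceps-enriched genes 0.54 and 0.62, which added slow tissue would also give. So this and a shift of fibre type in the cKO, the biological alternative the design gives, cannot be told apart with these shares, which differ with the controls used.

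Quadriceps and soleus of 1 genotype and number deviated together: 99 of 416 variable genes had r above 0.8 across the 12 animals, against at most 16 in 100 shuffles. Strain variants that segregate between the animals were tested through neighbours: 39.4% of these genes had another within 5 Mb and 95% of random draws from the variable genes reached up to 47.5%. The 99 genes were thus not more clustered than such draws. The pool of the draws included the 99 genes, and linked variants could make its other variable genes cluster as well. The test therefore cannot decide on blocks of linked variants, and it cannot see scattered variants that each change 1 gene. Picked after their values were seen, Apool and Gdpd3 had gaps between animals of up to 1.78 and 2.24 (log2) in quadriceps and 2.49 and 2.01 in soleus. For Sri the largest gaps were 0.24 and 0.17. Time of day at sampling may account for part, though its share of the 99 genes was not tested. The mean deviations of 2 clock genes and of 9 clock genes of the opposite phase ran against each other over the 12 animals (r = -0.89, permutation p = 6e-05, rho = -0.91, permutation p = 8e-05, r = -0.92 without the 2 animals farthest from the median). Genes of opposite phase do so wherever the clock state differs between animals, so this shows such a difference and not its cause. Control and cKO animals of 1 number had both clock means of the same sign for numbers 1, 2, 4 and 5, but not the 2-gene mean for number 6 (0.12 and -0.28) or the 9-gene mean for number 3 (-0.07 and 0.13), so the number may mark a shared time or day, which the sources used here do not give, and the animals behind these p are then not independent. Age, which the labels give as 40 to 42 days, and litter stay open and were not tested against this pattern.

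Other arrays apart from their group were soleus cKO 6, high in Myh3 (12.06), Myh4 (9.57), Ndrg4 (9.30) and Sqstm1 (10.13) and low in Prc1 (4.41) and the macrophage mean (6.02), and quadriceps control 4, low in Mybpc2 (11.81), Phka1 (9.94) and the fast fibre (12.24) and glycolysis means (10.58). Quadriceps control 3 was high in Cidec (8.68), Postn (8.76) and the adipocyte (9.25) and cell cycle means (4.88). Quadriceps cKO 2 was high in Cidec (9.65) and the adipocyte mean (9.87) and low in the thin filament mean (10.14). Quadriceps cKO 4 was high in the oxidative phosphorylation (10.15) and polyamine means (7.63) and low in Gadd45a (9.47), and quadriceps cKO 6 was low in Cxcl10 (4.91) and high in Fbxo31 (8.87). Soleus control 6 was high in Hadhb (11.08) and the endothelial mean (8.37) and low in the tendon mean (7.90), and quadriceps control 6 was low in Rny1 (8.74) and high in the Schwann cell mean (5.65). High single values were Aldh3a1 in quadriceps control 2 (5.69), Th in quadriceps control 1 (5.39) and Mfap5 in soleus control 3 (8.82), and low ones Csrp3 in quadriceps control 5 (7.20), Mfap5 in quadriceps cKO 5 (9.32) and Mcm6 in soleus control 5 (3.43).

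Of 132 genes named for the cKO comparisons or for the difference between muscles 82 passed the test of the difference itself, a count raised by those that were named because they passed it. The quadriceps change minus the soleus change, on the log2 scale, was above 0 for Aldh3a1 (3.44), Ostn (3.18), Myh4 (2.33), Pvalb (2.30), Krt18 (2.29), Rrad (2.28), Cxcl10 (2.23), Slc5a3 (2.06), Myh7 (1.93), Tnnc1 (1.76), Chrna1 (1.76), Myh1 (1.72), Tnni1 (1.72), Myh8 (1.66), Runx1 (1.66), Lrrc52 (1.63), Myl2 (1.57), Tecrl (1.53), Chrng (1.51), Csrp3 (1.44), Ephx2 (1.30), Thbs1 (1.29), Casq2 (1.28), Lgals3 (1.22), Ncam1 (1.18), Sln (1.13), Ttc9 (1.09), Lpl (1.04), Chrnd (1.03) and Myh2 (1.02). Smaller differences above 0 were those of Th (0.98), Fbxo30 (0.96), Gadd45a (0.93), Foxo1 (0.92), Lrtm1 (0.90), Lmod2 (0.90), Igf2 (0.83), Ccn2 (0.82), Myh11 (0.77), Cd36 (0.75), Fhl2 (0.74), Fst (0.71), Mpeg1 (0.68), Mkx (0.58), Flt1 (0.56), Postn (0.54), Eci1 (0.51) and Tnni2 (0.40).

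It was below 0 for Mybph (-4.0), Rny1 (-3.18), Cyp4f39 (-2.21), Actc1 (-2.13), Aimp2 (-1.92), Mstn (-1.85), Epgn (-1.79), Rbp4 (-1.78), Gamt (-1.74), Prkab2 (-1.73), Slc37a4 (-1.57), Muc15 (-1.54), Odf3l2 (-1.53), Chac1 (-1.45), Smox (-1.41), Mylk2 (-1.29), Gdf11 (-1.15), Smyd2 (-1.11), Jph2 (-1.09), Klhl40 (-1.02) and Ndrg4 (-1.0). For Mstn, Muc15, Epgn, Odf3l2, Cxcl10 and Tecrl at least 1 group mean lay at or near the dim limit, so their differences are not exact. The difference was closer to 0 for Odc1 (-0.97), Cd68 (-0.95), Nt5c1a (-0.92), Mrln (-0.84), Pdlim3 (-0.83), Map1lc3a (-0.70), Psmd4 (-0.66), Sqstm1 (-0.54), Psmd8 (-0.52), Psmc4 (-0.52), Ndufb2 (-0.41), Psmd11 (-0.41) and Xirp2 (-0.34). For 12 of the 31 lists the test of the difference passed, with median differences of 1.55 for slow fibre, 0.26 for fast fibre, 0.73 for embryonic, 0.41 for denervation, 0.22 for growth, 0.30 for fatty acid oxidation, 0.25 for matrix, 0.43 for endothelial, 0.37 for pericyte, 0.49 for tendon, 0.23 for endoplasmic reticulum chaperone and -0.33 for proteasome genes. Of these only the denervation list held with an estimated correlation (camera adjusted p = 0.0406).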

How the results depend on the processing

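Leaving out the 3 arrays of lowest weight, centring on the 75th percentile and the fixed block per animal for the difference are tests that were chosen only after the result was seen. Across the other settings 2549 of 2559 values for the named genes kept their direction and their side of the threshold, 6 lost the call (5 for Myh4 between muscles, adjusted p 0.0512 to 0.0905, and Car3 in soleus) and 4 gained it (Kdr in quadriceps). With single arrays left out 4700 of 4728 kept their side of the threshold, 25 lost and 3 gained the call, and no called value reversed; Fbxo32 in quadriceps, not called, changed sign without quadriceps control 6 or cKO 4. Gene lists kept their calls in 1601 of 1732 values across settings, with 92 lost and 39 gained, and in 2884 of 2976 with single arrays left out, with 36 lost and 56 gained. The estimated correlation left 2 of 18 called lists in quadriceps, 2 of 20 in soleus, 1 of 12 for the difference and 0 of 10 between control muscles. The count of genes whose change differed between the muscles (1966) was 3570 with array weights, 2952 with the animal as a random block, 3675 without the 3 arrays of lowest weight, 845 at an adjusted p under 0.01 and 914 with at least 1.5-fold, and 7 lists were called without those 3 arrays. Genes with opposite changes (117) numbered 326, 385 and 27 with weights, without the 3 arrays and at 0.01. At 0.01 the counts were 4243 in quadriceps, 2407 in soleus, 3537 between control muscles and 1395 shared in 1 direction, with 1.5-fold 1612, 1014 and 1253, and the unequal-variance test per gene called 3136 between control muscles. Stricter thresholds lower counts by construction; for the other settings the cause was not tested. With single arrays left out the counts ranged from 5692 to 7240 in quadriceps, 3235 to 4277 in soleus, 1576 to 2856 for the difference, 4745 to 5759 between control muscles and 81 to 197 for opposite changes (191 without quadriceps control 6, 197 without soleus control 1). The replicate block by number gave 6373, 3803 and 2099 genes in quadriceps, soleus and for the difference, and the fixed block per animal 2866 for the difference and 6211 between control muscles. Controls and cKO of a muscle are different animals that share a number and, but for quadriceps number 4, an age: same-number correlations were -0.15 to 0.17 in quadriceps (2 of 6 best with their own number) and 0.04 to 0.32 in soleus (4 of 6), and with the number as a block endoplasmic reticulum chaperones in soleus (0.0324) and oxidative phosphorylation for the difference (0.0285) were called. Of the blocked values, all 427 for named genes and 150 of 155 for lists kept their call; the others were the fast fibre list for the difference, oxidative phosphorylation and pericyte genes between control muscles and the pair just given. Age as a covariate gave 6375, 3771, 1980 and 5407 genes in the order above. Dim genes limit what the arrays can show: 3939 genes near background were not tested.

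Splits of the samples argue against chance for the 4 gene counts, though 1 of 100 is the lowest share they can give. Of 100 splits into groups of 6, only 1, the real one, called as many genes: 5333 in quadriceps against at most 1 in any other, 4237 in soleus against at most 1437, 2866 for the difference against at most 917, and 4055 between control muscles against at most 1950. Each split was fitted on its own arrays alone, so these counts differ from those of the main model. For the difference, each animal's quadriceps minus soleus values were split, which rests on the pairing inferred from the data. Of the 32 splits of the control arrays that part all 6 pairs, the real one called 4055 and the highest other 1.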

Other observations

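The gene sets here were chosen only after the result was seen, while the test around the Neb gene was written before. The sets were put together from values already seen and were not tested as sets; over all 15999 genes 3563 were higher in quadriceps and 2104 in soleus. Of 14 imprinted growth genes 12 rose and 1 fell in quadriceps, and 11 rose and none fell in soleus. Peg3 rose by 2.27 and 2.11 (log2, quadriceps and soleus), Zim1 by 2.19 and 1.47, Meg3 by 1.71 and 1.63, Cdkn1c by 1.71 and 1.21, Mest by 1.49 and 1.69 and Igf2r by 0.84 and 0.99, while Slc38a4 fell by 0.86 in quadriceps. Of 6 genes of desmosomes and simple keratins 5 were higher in quadriceps and 3 in soleus. Krt18 rose by 2.86 and 0.57 and Pkp2 by 0.51 and 1.42, and Krt8 rose by 1.12 in quadriceps and stood at -0.02 in soleus.

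Of 14 interferon response genes listed 9 were tested. In quadriceps 8 of 9 were higher and none lower, with Cxcl10 up by 2.36, Ifit1 by 1.45 and Irf7 by 0.91, while in soleus none of the 9 passed the test and the same genes stood at 0.13, -0.17 and 0.05. The difference between the muscles passed for 7 of the 9 (1966 of all 15999 genes), and for 6 under each other scaling. No called member of these 3 sets turned its direction under those scalings, while in quadriceps 7 interferon genes passed under each, and after median centring 4 desmosome and keratin genes did. In cKO quadriceps 6 Cxcl10 read 4.91, the lowest of its group, where the other 5 lay between 6.21 and 6.35.

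Variants linked to the targeted Neb locus could differ between cKO and control animals and change the expression of neighbouring genes. Within 10 Mb of Neb 3 of 43 genes (6.98%), Gpd2, Lypd6 and Psmd14, were called in both muscles in 1 direction, the names given after their values were seen. Windows of as many neighbouring genes elsewhere had a median of 14.0% and a 95th percentile of 23.3% over 1519 windows. Shared calls were thus not in excess near Neb. Per the labels the controls carry the conditional allele too, so the groups should largely share this region and the test had little to find. The neighbourhood of the Cre transgene, which the groups do not share, was not examined.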
